A study of Mus musculus with 2 samples.

How the data were processed

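Total RNA sequencing of mouse limb at embryonic day 12.5 was analysed from deposited tables for 2 biological replicates of 1 group, as the labels number them. RNA was extracted with the mirVana method, per the labels, and a manual for a SMARTer low-input kit is among the linked protocols. The deposited expected counts are estimated counts per gene and transcript that need not be whole, with shared reads split by the quantifier, per the file headers. The deposited TPM values are scaled to a fixed sum over all rows, spike-ins included, and use an effective length that was the length minus 99 nt, so genes shorter than that carry none. The deposited FPKM values are scaled by length and reads, per the file headers. The deposited percent values give the share of a gene held by each transcript, per the file headers. The genome build was mm10 and the annotation GENCODE M4, per the text files deposited with each sample. The aligner, the quantifier, their versions and the strand setting are not given in the sources used here.

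The gene tables held 69691 rows, of which 43346 were Ensembl genes, 97 spike-ins and 26248 numeric identifiers. Names and coordinates came from GENCODE M21, which uses the same assembly, by identifier without version, and 42462 Ensembl genes matched. Library totals were 29810026 and 29938721 expected counts, which were rounded for count tests. Intervals and floors (3 counts) cover counting error only, since no molecular identifiers are recorded. A chi-square per degree of freedom of 6.61 over 16995 genes showed that the libraries were not the same one deposited a second time.

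Genes counted as detected had a TPM of at least 1 in both libraries. Log values used a pseudocount of 0.1 TPM. With 1 group, edgeR's quasi-likelihood test could not be run. The biological coefficient of variation came from edgeR's estimateDisp with an intercept-only design and TMM scaling, over genes with at least 10 counts in both libraries. Libraries were compared gene by gene with an exact conditional binomial test over genes with at least 10 counts summed over both libraries, called at an adjusted p under 0.05 and a fold of at least 2. A gene pair was tested by the mean log2 ratio against 0.5 of the between-library difference in 10000 random pairs, each gene drawn from the 200 nearest in mean TPM. A gene list was tested by its median log2 ratio against 10000 random lists matched in the same way, where at least 3 members had a mean TPM of at least 1. Major transcripts were compared for genes with a mean TPM of at least 5 and at least 2 transcripts. Lists, pairs, tests and alternatives were fixed before the data were examined, except where stated.

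The text names the 3 highest members and the lowest of each list (the 10 highest for Hox genes), the genes of every pair, the 8 highest nuclear genes outside globins, ribosomal protein genes and structural RNAs, and the 8 genes with the largest fold in each direction among called genes of at least 5 TPM. Genes without a symbol were counted only, and a few genes that this rule takes are not reported. Ahsp and Dlx6os1 were not matched and are not analysed here.

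The gene-by-gene tests were tested on simulated data made from the 43346 real genes for the comparison of the replicate libraries. With counting error only, 100% of 100 genes changed 4-fold and 52% of 100 genes changed 2-fold were called, with 3 false calls among 18555 tested. The changed genes were drawn only from genes with counts well above the minimum of the test. These shares therefore do not cover genes near that minimum. A call needs an estimated fold of at least 2, so the share at a true fold of 2 reflects that limit and not only sensitivity. With a simulated coefficient of variation of 0.1 and no change, 0.0990 was recovered, and the binomial test called 77 of 18601 genes and edgeR's exact test 0. An adjusted p from the binomial test therefore does not cover replicate spread. Alternatives changed the scaling, filters, pseudocount, unit and matching, and left out each replicate. Tools were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.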

Results

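Total RNA was sequenced from the limbs of mouse embryos of strain B6NCrl at embryonic day 12.5, when the digits and cartilage models of the limb are forming. The labels name 1 group of 2 biological replicates. Replicate 1 was a pool from 88 embryos and replicate 2 a pool from 68 embryos, both of mixed sex and both started from 10 ng of RNA above 200 nt. The labels do not separate forelimb from hindlimb and give no second condition, so the comparisons below are between genes within the limb and between the replicate libraries. The deposited expected counts summed to 29810026 and 29938721. Levels are in TPM and are given as mean ± SD over the replicates (n = 2) unless stated.

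Of 43346 Ensembl genes, 14507 reached a TPM of 1 in both libraries, and 12702 of these were protein-coding. The annotated nuclear genes with the highest levels, outside globins, ribosomal protein genes and structural RNAs, were the histone gene Hist1h2ap (5693 ± 596), Actb, which encodes beta-actin (5397 ± 154), Gm28437 (5160.5 ± 72.3), the nuclear noncoding RNA Malat1 (4961 ± 750.1), the prolyl isomerase gene Ppia (4802 ± 255), Gm42418 (4458 ± 389.7), Gm10123 (4239 ± 413) and Gm26917 (4119 ± 375). Gm28437 and Gm10123 are annotated as pseudogenes and Hist1h2ap belongs to a multigene family, so their levels depend on how shared reads were split. Gm26917 and Gm42418 lie side by side on chromosome 17 and are annotated as long noncoding RNAs. Together they took 1.24% of the counts in replicate 1 and 1.41% in replicate 2, and the origin of their reads was not tested. Ribosomal protein genes took 2.27% of the counts in replicate 1 (95% exact interval 2.27 to 2.28) and 2.35% in replicate 2 (2.34 to 2.35). Mitochondrially encoded genes took 1.16% and 1.07%, globins 0.602% and 0.599%, and replication-dependent histone genes 0.175% and 0.209%.

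Transcription factors of the limb mesenchyme were all present. Each of the 32 listed genes reached a TPM of 1 in both libraries, with a median of 22.9 TPM. The homeobox gene Msx1 was the highest (395 ± 21.6), followed by the paired-related genes Prrx2 (166 ± 6.80) and Prrx1 (165 ± 3.17), and Zbtb16 was the lowest (1.25 ± 0.0636). Msx1 was 6.97-fold above Msx2 (log2 ratio 2.80 ± 0.06), whereas Prrx1 and Prrx2 were not separated (adjusted p = 0.989). Without length scaling, Prrx1 was called above Prrx2 (log2 ratio 2.22). Hand2, which marks the posterior limb, was 5.32-fold above the anterior gene Alx4 (log2 ratio of Alx4 over Hand2 -2.41, and -1.16 without length scaling). Meis1 was 1.51-fold above its paralog Meis2, and Meis2, a gene of the proximal limb, was below the distal gene Hoxa13 (log2 ratio -0.58 ± 0.20), a call that was lost without length scaling. The dorsal gene Lmx1b (7.68 ± 0.643) and the ventral ectodermal gene En1 (1.53 ± 0.0212) differed by a log2 ratio of 2.25 ± 0.14, which did not pass the test (adjusted p = 0.0579). It was called with a pseudocount of 1 (1.77), without length scaling (3.16) and with posterior means (2.27).

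Genes that distinguish forelimb from hindlimb were both represented. Pitx1, a hindlimb regulator (ENSMUSG00000021506.7, chromosome 13, 55825051 to 55836192), was measured at 158 ± 21.6 TPM, 4.52-fold above the hindlimb gene Tbx4 (ENSMUSG00000000094.8, chromosome 11, 85886422 to 85916097; 34.7 ± 3.44). The forelimb gene Tbx5 (ENSMUSG00000018263.8, chromosome 5, 119832668 to 119885219) was at 29.6 ± 7.82 TPM, 5.37-fold below Pitx1 (log2 ratio -2.43, and -1.57 without length scaling). Tbx5 was above Tbx4 in replicate 1 (35.2 against 32.3 TPM) and below it in replicate 2 (24.1 against 37.1 TPM), so no difference between them was called (log2 ratio -0.25 ± 0.53; adjusted p = 0.0322 before the direction was required to be the same in both). Hoxc11 had the lowest level of this list (3.64 ± 1.06).

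Hox expression was dominated by posterior genes of clusters A and D. Hoxa10 was the highest (ENSMUSG00000000938.11, chromosome 6, 52231197 to 52240854; 236 ± 16.7 TPM), followed by Hoxd12 (101), Hoxa11 (78.0), Hoxd13 (70.8), Hoxa9 (64.1), Hoxd11 (48.9), Hoxd10 (34.0), Hoxa13 (28.0), Hoxc10 (17.4) and Hoxd9 (15.4). Summed over paralog groups 9 to 13, cluster A reached 406 ± 27.0 TPM, cluster D 270.2 ± 22.7, cluster C 29.7 ± 3.03 and cluster B 1.06 and 0.890 in replicates 1 and 2. Clusters A and D together were 22.0 ± 0.475 times clusters B and C. Of 39 Hox genes, 27 reached a TPM of 1 in both libraries, and Hoxb1 and Hoxb13 shared the lowest mean at 0.0150 TPM. Hoxa13, a gene of the future hand and foot, was 2.78-fold below Hoxa11, which marks the middle segment, while Hoxd13 was 1.45-fold above Hoxd11. Hoxd13 was 1.43-fold below Hoxd12 and 2.52-fold above Hoxa13. The strand setting of the counting is not given in the sources used here, so reads of antisense genes in these clusters could not be told apart.

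**Figure D1:**
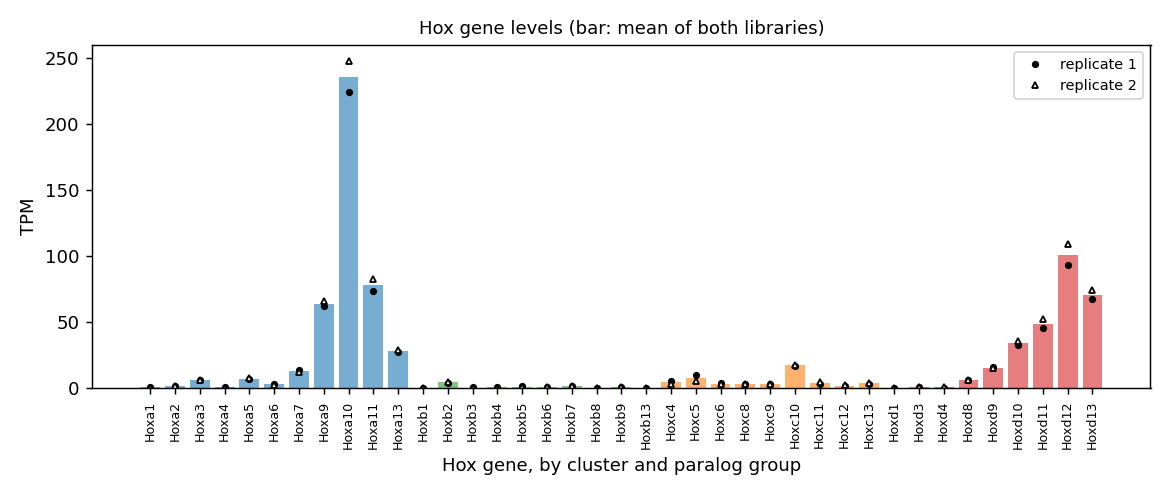
TPM (vertical axis) of each Hox gene, ordered by cluster and paralog group (horizontal axis). Bars are the mean of both libraries, filled circles replicate 1 and open triangles replicate 2, and Hoxa10 is the highest at 224 and 248 TPM.

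Genes of 6 signalling lists were measured. In the hedgehog list 9 of 11 genes reached a TPM of 1, led by Smo (49.9), Gli3 (43.1) and Sufu (36.9). The ligand Shh (ENSMUSG00000002633.3, chromosome 5, 28456815 to 28467256) was the lowest at 0.0800 and 0.0700 TPM in replicates 1 and 2. Gli3, which acts largely as a repressor, was 4.66-fold above the target gene Gli1 (log2 ratio 2.22, and 2.96 without length scaling). In the FGF list 14 of 16 genes reached a TPM of 1, led by Fgfr1 (122), Fgfr2 (102) and the feedback phosphatase gene Dusp6 (96.3), with Fgf4 lowest (0.410). Fgf8, the ligand of the apical ectodermal ridge, was 2.03-fold above mesenchymal Fgf10 per unit of length, and the order turned without length scaling. Fgfr1 was 1.19-fold above Fgfr2. All 19 BMP genes were detected, led by the target genes Id3 (546), Id2 (299) and Id1 (262). The antagonist Grem1 was lowest (2.85) and lay 3.17-fold below Nog, a call lost without length scaling. Bmp4 (30.7) and Bmp2 (31.8) were not separated (adjusted p = 0.600), but Bmp4 was called below Bmp2 without length scaling (log2 ratio -1.02). All 19 WNT genes were detected, from Ctnnb1 (518), Sfrp2 (256) and Wnt5a (162) down to Rspo2 (2.65). In the retinoic acid list 14 of 16 were detected, led by the binding protein genes Crabp2 (534) and Crabp1 (275) and the receptor gene Rarg (114), with Aldh1a1 lowest (0.110). The synthesis gene Aldh1a2 was 2.91-fold above the breakdown gene Cyp26b1 (log2 ratio 1.54, and 0.46 without length scaling). In the interdigit list all 10 genes were detected, led by Bax (173), Aldh1a2 (94.0) and Mmp11, with Bak1 lowest (3.60).

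The skeleton was represented by early cartilage, with little sign of hypertrophic cartilage or bone. Col2a1, the main cartilage collagen (ENSMUSG00000022483.12, chromosome 15, 97975602 to 98004695), was at 411 ± 59.2 TPM, and the cartilage regulator Sox9 (207 ± 1.03) and Col9a3 (177 ± 13.2) followed. Col2a1 was 1.54-fold above Col1a1 and 807-fold above Col10a1, the collagen of hypertrophic cartilage (0.410 TPM). The latter log2 ratio of 9.66 was 8.18 with a pseudocount of 1 and 10.39 without length scaling. Of the chondrogenic list 19 of 20 reached a TPM of 1 in both libraries, and Snorc was the lowest (2.67). Of the hypertrophic and osteogenic list 7 of 13 did, led by Pth1r (64.5), the osteogenic regulator Runx2 (8.35) and Spp1 (4.49), and Mmp13 was listed at 0. Sox9 was 24.9-fold above Runx2, which was 2.68-fold above Sp7. Joint interzone genes were led by Gdf5 (52.2), Osr2 (48.2) and Osr1 (46.4), with Prg4 lowest (0.620). Tendon and loose connective tissue genes were all detected, led by Lum (124), Pdgfra (117) and the tendon regulator Scx (65.1), with Tnmd, a gene of mature tendon, lowest (1.57). All 25 matrix genes were detected, led by Col3a1 (744), Sparc (397) and Col1a2 (388), with Has2 lowest (3.75).

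Muscle genes covered commitment and early differentiation. Myog, a regulator of differentiation, was at 94.5 ± 4.70 TPM, 2.25-fold above the commitment factor Myod1 (42.0 ± 2.90). The progenitor genes were low. Pax3 (1.39 ± 0.113) was 3.31-fold above Pax7 (0.350 ± 0.0141), the lowest of the list, a call lost with a pseudocount of 0.01. That log2 ratio was 1.73, and 1.96 with a pseudocount of 0.01 and 0.82 with 1. Myf5 was above Myf6 (log2 ratio 3.91 ± 0.14, 2.89 with a pseudocount of 1 and 4.63 without length scaling). Of the contractile genes 16 of 17 reached a TPM of 1, led by Actc1 (344), Tnnt1 (158) and Myl1 (142), while Ckm was lowest (0.220). Embryonic myosin Myh3 was 7.08-fold above perinatal Myh8.

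The covering ectoderm, vessels and blood were all detected. Basal keratin genes Krt14 (127 ± 7.40) and Krt5 (87.7 ± 3.05) and the p63 target Perp (53.3 ± 0.658) led the ectoderm list, and Krt14 was 12.9-fold above the simple keratin gene Krt8. In the ridge list 10 of 12 reached a TPM of 1, led by Bambi (31.6), Trp63 (23.1) and Fgf8 (14.4). Endothelial genes were led by Egfl7 (66.5), Plvap (50.1) and Esam (23.5), with Robo4 lowest (6.55), and Pecam1 was 16.4-fold above the leukocyte gene Ptprc (log2 ratio 4.03, 3.33 with a pseudocount of 1 and 3.44 with posterior means). Macrophage genes were led by Pf4 (42.5), C1qb (16.0) and Fcer1g (15.4). The embryonic globin gene Hbb-y reached 7149.8 ± 18.0 TPM, 8.39-fold above adult Hbb-bt and 13.9-fold above Hbb-bh1, and Hba-x was at 1318 ± 32.9. Adult alpha globin genes Hba-a2 (5593) and Hba-a1 (2574) are near-identical copies, as are Hbb-bt and Hbb-bs (404), so the split within each pair is uncertain. Erythroid genes were led by Alas2 (33.4) and Slc4a1 (20.1), with Tal1 lowest (1.35).

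Nerve and pigment markers were low. Schwann cell precursor genes were led by Ngfr (21.2), Erbb3 (13.3) and Fabp7 (4.73), with S100b lowest (0.365). Neuron genes were led by Gap43 (23.5), Nefm (10.1) and Tubb3 (9.84), with Elavl3 lowest (0.0900), and Sox10 was 2.64-fold below Tubb3. Of the melanoblast genes Kit (10.6) and Mitf (1.05) reached a TPM of 1 in both libraries, Pmel was at 0.785 and Mlana was lowest. Markers of neighbouring organs were also measured. Liver genes were led by Trf (8.93), Afp (3.29) and Apoa1 (2.36), with Fgb at 0.0350. Heart genes were led by Tnnt2 (31.9), which embryonic skeletal muscle also expresses, Tnni3 (4.29) and Myl7 (1.52), and Nkx2-5 was listed at 0. Of 10 genes of other trunk organs none reached a TPM of 1, and Wt1 was the highest (0.545).

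Cell cycle genes were abundant, with a median of 165 TPM over 21 genes, led by Cdk1 (369), Rrm2 (317) and Top2a (294), with E2f1 lowest (22.6). Imprinted genes were led by Nnat (1563), Gnas (1545) and Mest (1288), with Usp29 lowest (0.320). Igf2 was 1.49-fold above its reciprocally imprinted neighbour H19, and Dlk1 was 4.08-fold below Meg3. Stress genes were led by Hsp90aa1 (685), Ier2 (116) and Dnajb1 (78.2), while Fos was at 1.95 and Hspa1b at 0.0800. Hypoxia genes were led by Ldha (1329), Pgk1 (273) and Bnip3, with Car9 lowest (0.980). After Malat1, the long noncoding RNAs were led by H19 (485) and Meg3 (456), and Hotair, transcribed from the Hoxc cluster, was lowest (2.25). Of the small structural RNAs, Rn7sk (370.0) and Rpph1 (123) led and Terc was lowest (1.40).

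In all, 31 of 35 gene pairs differed in the same direction in both libraries by more than matched random pairs differed between libraries (resampling, two-sided, Benjamini-Hochberg adjusted over the pairs). The smallest adjusted p was 0.000185, the least that the number of draws allowed, and it applied to Hoxa13 and Hoxa11, Hoxd13 and Hoxd11, Col2a1 and Col1a1, Col2a1 and Col10a1, Myod1 and Myog, and Hbb-y and Hbb-bt, among others. The test covers replicate error and not gene-specific bias of the assay, and an exact sign-flip test of 2 libraries cannot go below p = 0.5.

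Between the replicate libraries, cartilage genes were lower and neuron genes higher in replicate 2. The chondrogenic list had a median log2 ratio, replicate 2 over replicate 1, of -0.43 (adjusted p = 0.00220), with 18 of 20 genes lower in replicate 2. Among members of at least 5 TPM the median was -0.19. Matn1, a cartilage matrix gene, was at 25.3 and 10.2 TPM, Acan at 6.26 and 3.13, Comp at 4.34 and 2.01 and Epyc at 4.63 and 1.53, while Sox9 was at 208 and 206. The neuron list had a median of 0.63 (adjusted p = 0.00220), with 8 of 9 genes higher in replicate 2. The neurofilament gene Nefl was at 4.19 and 10.5 TPM and the peripheral neuron gene Prph at 0.160 and 3.94.

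In all, 14 of 33 lists lay outside matched random lists. Random lists were drawn gene by gene, so the adjusted p of every list test treats members as independent. It does not cover genes that vary together between 2 pools. Lower in replicate 2 were hypertrophic and osteogenic genes (-0.42), hedgehog genes (-0.29), tendon and loose connective tissue (-0.21), matrix (-0.07), ectoderm (-0.13), imprinted genes (-0.12), muscle contractile genes (-0.09), myogenic regulators (-0.13), macrophage genes (-0.16) and liver genes (-0.57). Higher in replicate 2 were limb type regulators (0.24), where Isl1 was at 7.31 and 14.1 TPM but forelimb Tbx5 at 35.2 and 24.1, and small structural RNAs (0.47). Some of these lists were small, with 4 tested members each for liver and small structural RNAs and 6 for limb type regulators. Random lists matched to the liver list spanned -0.37 to 0.41. The proliferation list (0.02, adjusted p = 0.465) and the limb mesenchyme list (-0.04, adjusted p = 0.149) did not pass the test. The calls of myogenic regulators and macrophage genes were lost in most other settings, that of hypertrophic and osteogenic genes with TMM-scaled counts (medians of -0.08, -0.10 and -0.25 with these counts), and those of matrix genes and small structural RNAs when random lists were matched on length too.

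**Figure D2:**
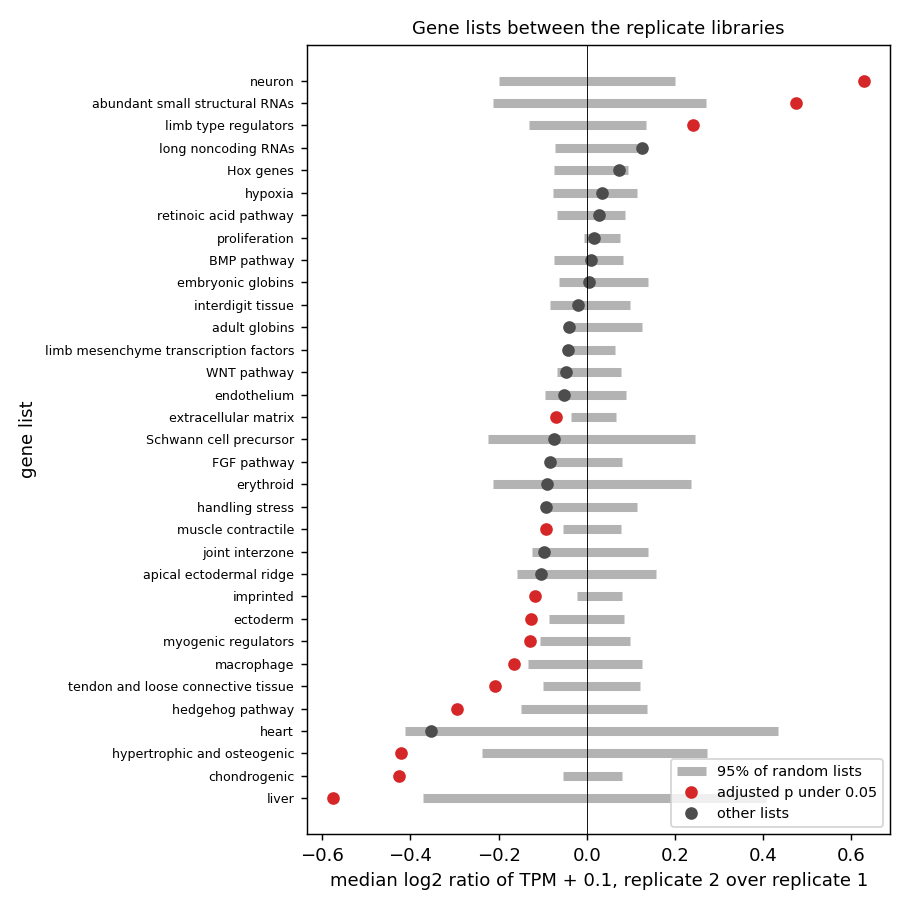
Median log2 ratio of TPM + 0.1, replicate 2 over replicate 1 (horizontal axis), of each gene list (vertical axis). Points are list medians, red where the adjusted p was under 0.05, and grey bars span 95% of matched random lists, with neurons highest at 0.63 and liver lowest at -0.57.

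Gene by gene, 313 of 18580 genes differed at least 2-fold between the libraries beyond counting error (exact binomial test, two-sided, Benjamini-Hochberg adjusted), 178 higher in replicate 2 and 135 higher in replicate 1. With no fold limit, 1441 were higher in replicate 2 and 1552 in replicate 1. With a spread estimated from the same 2 libraries, and so not independent of the difference tested, edgeR's exact test called 79, and 73 were called among 13645 genes with at least 100 counts. The pools are separate biological pools, and a test on 2 libraries compares those libraries and not conditions. Among genes of at least 5 TPM, those with the largest fold higher in replicate 2 were Hist1h2aj (at least 70.3-fold, against a floor of 3 counts in replicate 1), Adnp (5.11-fold), Gm10193 (4.00-fold), Eid2 (3.59-fold), Selenon (3.31-fold), Gm12184 (3.29-fold), Cdk2ap1 (3.12-fold) and Gm15920 (3.04-fold). Higher in replicate 1 were Gm26602 (6.47-fold), Snora73b (3.92-fold), Tom1 (3.04-fold), Matn1 (2.48-fold), Rps18-ps3 (2.33-fold), Gm15421 (2.27-fold), Gm10698 (2.24-fold) and Gm28052 (2.22-fold). The first 2 are short genes with few counts. Gm26602 (285 nt) had 54.3 and 8 expected counts in replicates 1 and 2, and Snora73b (205 nt) had 17.4 and 4.27. Hist1h2aj is annotated as a pseudogene, and it and the other pseudogenes named share sequence with other copies, so their values are uncertain. The protein-coding genes named as higher in replicate 2 (Adnp, Eid2, Selenon, Gm12184 and Cdk2ap1) each held a 100-nt window of 87% to 91% GC. No gene named as higher in replicate 1 held one above 82%, and the protein-coding Gm26602, Tom1 and Matn1 reached 64%, 67% and 71%. The pseudogenes named as higher in replicate 2, Hist1h2aj, Gm10193 and Gm15920, reached 78%, 52% and 59%. Whether such windows shaped these folds stays open, so the folds are not shown to be differences between the pools.

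Over 15112 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 0.1) was 0.963 and Spearman's rho 0.989, across genes, which are not independent replicates. The biological coefficient of variation was 6.98%. Genes under 300 nt scattered most, with 51.4% within 2-fold against 98.5% of longer genes. The most abundant transcript was the same in both libraries for 92.5% of 7996 genes. Wnt5a, Fgf8, Meis2 and Fgfr3 were among 13 of 224 listed genes where it was not, named after their values were seen. Of 96 spike-in RNAs, 83 had a count in replicate 1, 83 in replicate 2 and 80 in both, with r = 0.991 across spike-ins, and they took 3.28% of the counts in replicate 1 and 2.30% in replicate 2.

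**Figure D3:**
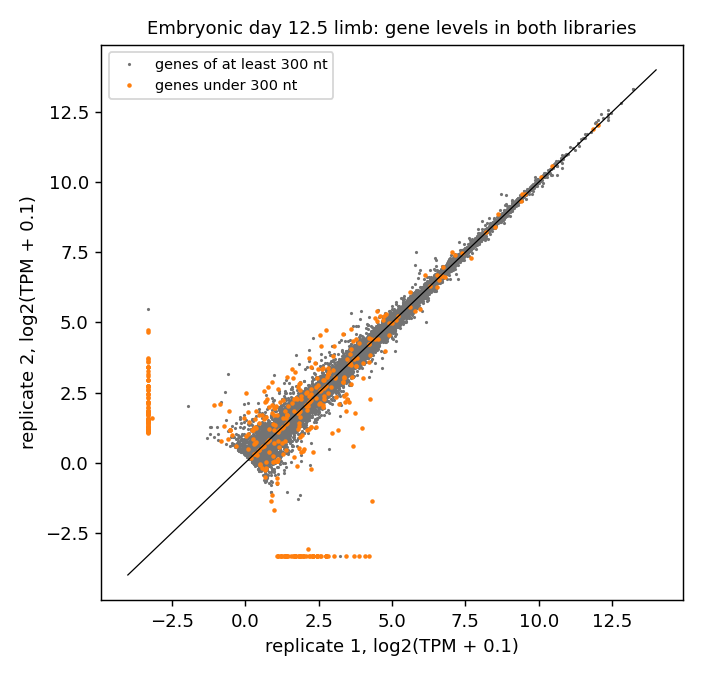
Level of each gene with a mean TPM of at least 1 in replicate 1 (horizontal axis) and replicate 2 (vertical axis), as log2(TPM + 0.1). Grey points are genes of at least 300 nt, orange points shorter genes, and the line marks equal levels, around which r was 0.963.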

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

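Counts appeared in identifiers that no gene list or pair used. The 26248 rows with numeric identifiers, which the files do not pair with names, summed to 36 expected counts in replicate 1 and 42 in replicate 2. Of these rows, 9 had a count in either library. Their median length was 73 nt and 63 of them reached 100 nt, so nearly all were too short to have an effective length. The 884 Ensembl genes without a match in GENCODE M21 summed to 89309 and 98427 expected counts, and 101 of them reached a TPM of 1 in both. These unmatched genes were included where all genes were counted.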

How the results depend on the processing

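The length filter of 300 nt, the removal of genes with GC-rich windows and length matching were chosen after the data were seen. Without length scaling (CPM), Tbx5 over Tbx4 changed sign to a log2 ratio of 0.11, Fgf10 over Fgf8 to 1.14 and Prrx1 over Prrx2 to 2.22, since that setting by construction favours longer transcripts, and the Hox cluster ratio moved to 23.7. The replicate agreement moved to r = 0.986 with a pseudocount of 1, 0.925 with 0.01, 0.973 with no filter, 0.993 for CPM, 0.991 for posterior means and 0.989 for genes of at least 300 nt. The spike-in r was 0.997 with a pseudocount of 1. The coefficient of variation, 0.0698 as reported, was 0.0699 with DESeq2 size factors, 0.0701 with library totals, 0.0708 from 1 count, 0.0651 from 100 counts and 0.0663 for protein-coding genes. Genes differing between the libraries numbered 313, against 73 from 100 counts, where fewer genes were tested, 2993 at any fold and 79 with edgeR's exact test. As shares of TPM, spike-ins took 6.58%, mitochondrially encoded genes 2.28%, globins 1.84%, ribosomal protein genes 6.27% and histone genes 0.772%, which weights short genes more. The same major transcript was found for 90.1% of genes from 1 TPM, 94.1% from 20 TPM and 99.1% where it held at least 60%. The cause was not tested where none is named. Results that need both libraries have no value with 1 left out. Without replicate 2, the uncalled pairs Tbx5 over Tbx4 (0.12), Bmp4 over Bmp2 (0.10) and Prrx1 over Prrx2 (0.06) also changed sign, within 1 SD, as a value with 1 of 2 libraries left out always is. With these 3, 82 comparisons for leading results and 167 for the rest stayed within their threshold or spread. These tallies include all such values of pairs, count shares and the Hox ratio with 1 library left out. Their outcome was fixed in advance, so the tallies overstate how stable the results were. Called lists numbered 14, and 10 to 12 under the alternatives, with chondrogenic and neuron lists called in each. Joint interzone genes were called only at a mean TPM of at least 5 (median -0.19, adjusted p = 0.0196). With matching on length as well, 10 were called, without matrix, small structural RNA, myogenic regulator and macrophage genes. Of the pairs outside the leading set, Meis2 over Hoxa13 and Grem1 over Nog lost their calls without length scaling, and Pax3 over Pax7 with a pseudocount of 0.01, where its log2 ratio was larger (1.96). Calls were gained for Lmx1b over En1 with a pseudocount of 1, without length scaling and with posterior means. They were also gained for Bmp4 over Bmp2 and for Prrx1 over Prrx2 without length scaling.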

Other observations

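The test of the sensory ganglion list was written before its result was seen, and the other tests below after. The sensory ganglion, motor neuron and neural tube lists were written after the report's lists had been examined. Motor neuron genes summed to 108 and 123 counts in replicates 1 and 2, and neural tube progenitor genes to 30 and 15. Too few members of either list reached a mean TPM of 1 for the list test.

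Neuron genes were higher in replicate 2. More nerve trunk tissue stays open, as the Schwann cell precursor list had a median log2 ratio of -0.0748, inside the random range of -0.22 to 0.25, with 3 members higher and 4 lower in replicate 2, Fabp7 (2.42 and 7.04 TPM) and Sox10 (3.66 and 3.47) among them. More sensory ganglion tissue stays open too. The 7 testable members of that list had a median of -0.0751, inside the random range of -0.22 to 0.22. This met the bound set beforehand against the explanation, and the choice to leave it open was made after that result. Of these members 3 were higher and 4 lower in replicate 2, Uchl1 (45.3 and 54.2 TPM) and Ntrk2 (2.62 and 1.84) among them. Members such as Uchl1 and Tac1 (10.5 TPM in replicate 1) had a level that could hide a small share. Of the 12 members below the level of the test, seen afterwards, 8 had more counts in replicate 2 and 3 fewer, among them Avil (6.75 and 40.8) and Pou4f1 (13 and 40). The design has 1 group, so no biological difference between groups was tested.

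Cartilage genes were lower in replicate 2. A trend with gene length is argued against as the whole cause, since the list median lay -0.366 from the lower bound of lists matched on level and length. A larger forelimb share in the replicate 1 pool stays open for the list as a whole, since it was drawn from the values that test it, with Tbx5 1.46-fold (95% interval 1.38 to 1.55) higher in replicate 1, Tbx4 1.16-fold (95% interval 1.09 to 1.24) and Pitx1 1.23-fold (95% interval 1.18 to 1.27) higher in replicate 2. It stays open too for the 5 genes that differed at least 2-fold, Acan, Matn1, Comp, Snorc and Epyc. All 5 had intervals beyond the fold of Tbx5, which met the bound set against this explanation. These genes had been selected by a larger fold, and the choice to leave the explanation open was made after that result. A later stage of the replicate 1 pool stays open, since Hbb-bt over Hbb-y differed by 0.0312 (log2), within the limit of 0.29.

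The last pattern is the set of 178 genes at least 2-fold higher in replicate 2. A GC-rich stretch (a 100-nt window of at least 85% GC) was held by 11.8% of 170 genes with a sequence, so it cannot account for most of the set. The share among level-matched genes was 7.26% (two-sided Fisher's exact p = 0.0360). This excess was short of the doubling set for the test after the data had been seen. Whether such windows added to the set stays open. Among the 31 with a mean TPM of at least 5, a part taken after the genes had been seen, the share was 38.7% against 9.69% (p = 1.88e-05, two-sided Fisher's exact test), yet 1.32% of all genes that held one at that level were called. This stays open, because the window and its limit were set after the windows of such genes had been read in an earlier look at protein-coding genes with at least 200 counts. GC content of the whole transcript stays open. The set's median of 50.1% lay inside the 48.0% to 50.8% of random sets matched on level, so no shift of the whole set was seen. With quartiles of 44.9% and 55.2%, that median cannot rule out an effect on a part of the set. The median log2 ratios of all genes highest and lowest in GC, -0.0166 apart, decide nothing about it. Of the 170 genes with a sequence, 46.5% had a posterior SD of 0 in both libraries, against 68.3% of level-matched genes. This share met the bound set in favour of reads shared between genes. That bound was written after the data had been seen, so the explanation stays open.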
